A study of Mus musculus with 8 samples.

How the data were processed

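Gene expression was measured by RNA sequencing in 8 libraries of spheroids from the mouse mammary epithelial lines EpH4 and EpH4-AS, without and with PM2.5, with 2 libraries in each of 4 groups. Per the labels, polyadenylated RNA was sequenced in 1 batch. The counts were made by the authors as raw whole numbers of reads per gene on GRCm39, and the 8 count columns of both count tables held equal values. RPKM values were made by the authors as counts scaled to the length of exons and to the reads of the library, and the total of reads that they imply was larger than the sum of the counts. The authors' tables per library also held total gene reads, a count wider than exons, from which the share of reads outside exons was taken. The aligner, the counting tool and the annotation release are not given in the sources used here.

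Of 25413 genes, 19932 had a count, and 13716 passed filterByExpr with 99.964% of all counts. Counts were scaled by TMM and fitted in R 4.3.3 with edgeR 4.0.16 as a quasi-likelihood model of the 4 groups with 4 residual degrees of freedom. The common dispersion was 0.00218, a biological coefficient of variation of 4.67%. Contrasts gave the PM2.5 effect in each line, EpH4-AS against EpH4 without and with PM2.5, and the interaction, which makes 5 tests per gene. P values were adjusted per contrast by Benjamini-Hochberg, two-sided, with a threshold of 0.05, and log2 CPM used a prior count of 2. Groups were read from the labels. The groups, comparisons, gene lists and the rule for naming genes were set before the data were examined.

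Gene groups were 40 lists, of which 39 with at least 5 measured members were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Genes were named by a rule. For the PM2.5 effect in each line and for the untreated lines, it took the 8 largest rises and 8 largest falls among genes past the threshold, at 5 CPM or more in the higher group, with both libraries of a group above both of the other. For the exposed lines it took 5 and 5, and for the interaction the 10 smallest p values. Predicted gene models and annotated pseudogenes were passed over. Of each list described, up to 4 members with the smallest adjusted p were eligible, and Cyp1a1, Cyp1b1, Tiparp, Hmox1, Nqo1, Mt1, Mt2, Il6, Cxcl1, Cdh1 and Vim were named always. A few eligible list members are not reported here. A fold against a group with 0 counts was taken against 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% counting interval was computed. GENCODE M21 annotation, on GRCm38, served only for gene types and the coding share of transcripts.

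Total counts per library ran from 15393256 to 27765982. On simulated data with known changes, made for the PM2.5 effect in EpH4 over 13573 genes, 86.6% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes were recovered, and 20 of 208 calls (9.62%) were false. For the interaction the recovered shares were 65.7%, 82.1% and 83.3%, and 10 of 164 calls (6.10%) were false. A raised list of 30 genes was called, and 0 of 20 random lists were. The simulated genes were drawn independently of each other, so this does not test list calls where genes of a list vary together.

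The alternatives were DESeq2 size factors in edgeR, library totals, the DESeq2 1.42.0 Wald test, no filter, a stricter filter of 1 CPM in 2 libraries, a block for the replicate number, a fit to 2 groups only, TREAT against a 1.5-fold change, limma-trend on log2(RPKM + 1), and leaving out each library in turn. Fits without mitochondrially encoded genes, with EpH4 libraries thinned to the mean EpH4-AS total, with an offset for coding share and with a crossed replicate block were chosen after seeing the data. A lone library left in a group was assumed to vary like the other groups. Genes with a count below the filter were left out of the tests.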

Results

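Polyadenylated RNA was sequenced from spheroids, rounded cell aggregates grown in culture, of 2 mouse mammary epithelial cell lines. EpH4 is the wildtype line in the labels, and EpH4-AS is described there as malignantly transformed. Spheroids of each line were left untreated or exposed to PM2.5, fine airborne particulate matter, at a dose and for a time that the labels used here do not give. The 8 libraries formed 4 groups of 2, with 1 sequencing batch in the labels. Total counts per library were 27765982 and 25687434 in untreated EpH4 and 26457809 and 24608176 in EpH4 with PM2.5. In EpH4-AS they were 16356285 and 15393256 untreated, and 17131588 and 18334052 with PM2.5. Levels below are TMM-normalised CPM, counts scaled to a common library total, as mean ± SD over the 2 libraries of a group (SD, n = 2). Log2 fold changes are given with a standard error derived from the test. It is the size of the log2 fold change over the square root of the F statistic. Adjusted p values are from the edgeR quasi-likelihood test unless another tool is named. The labels do not say whether the 2 libraries of a group came from separate cultures, so these p values measure the spread between these libraries, which may be technical.

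Of 25413 genes in the count table, 19932 had a count and 13716 passed the filter on low counts. Log2 CPM of the 2 libraries of a group correlated across genes with Pearson's r from 0.994 to 0.996 over 4 pairs. Across treatments within a line r lay between 0.987 and 0.992 over 8 pairs, and across lines between 0.701 and 0.717 over 16 pairs. The first principal component held 96.0% of the variance and separated the lines. Mitochondrially encoded transcripts took 2.47 ± 0.364% of counts in untreated EpH4, 4.63 ± 0.563% in EpH4 with PM2.5, 0.233 ± 0.0193% in untreated EpH4-AS and 0.286 ± 0.0229% in EpH4-AS with PM2.5 (SD, n = 2). Reads assigned to genes but lying outside exons made up 11.8 ± 0.706% and 11.96 ± 0.741% of gene reads in EpH4 without and with PM2.5, against 3.47 ± 0.107% and 3.51 ± 0.118% in EpH4-AS (SD, n = 2).

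The first comparison asked which genes differed between PM2.5-exposed and untreated spheroids of the wildtype line. In EpH4, Hmox1 (heme oxygenase 1, which degrades heme; ENSMUSG00000005413, chromosome 8, 75820249 to 75827217, GRCm39) rose from 967 ± 54.4 to 2019 ± 251 CPM (SD, n = 2), a 2.09-fold change (log2 1.06 ± 0.08, adjusted p = 1.17e-06). Itgb4, the integrin beta 4 subunit of hemidesmosomes (ENSMUSG00000020758, chromosome 11, 115865535 to 115899238), rose 4.67-fold, from 13.6 ± 0.989 to 63.8 ± 0.815 CPM. Tfrc, the transferrin receptor that imports iron (ENSMUSG00000022797, chromosome 16, 32427738 to 32451612), fell from 257 ± 50.1 to 93.3 ± 9.10 CPM (log2 -1.46 ± 0.10, adjusted p = 7.77e-07). Of the gene lists, 30 of 30 mitosis, 23 of 27 NRF2 antioxidant, 13 of 22 NF-kB and 13 of 13 mitochondrially encoded genes rose, and 32 of 46 ribosomal protein and 17 of 26 hypoxia genes fell. With an estimated correlation between the genes of a list, 0 of 39 lists were called here. The test called 3726 of 13716 genes, 1956 higher and 1770 lower with PM2.5, of which 385 differed by more than 2-fold (271 higher, 114 lower). The 2-fold count was 508 and 233 without EpH4 untreated replicate 1 or 2, 222 by the DESeq2 Wald test, 164 when tested against a 1.5-fold change and 67 by limma-trend on RPKM.

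The 8 genes with the largest rises by the rule fixed for naming genes were H2bc4 (log2 2.67 ± 0.16), Gsta3 (2.501 ± 0.13), H2ac6 (2.40 ± 0.25), Itgb4 (2.22 ± 0.07), H2bc8 (2.03 ± 0.29), Cxcl10 (1.98 ± 0.25), Aldh3a1 (1.91 ± 0.19) and Inpp5d (1.87 ± 0.20). Aldh3a1, an aldehyde dehydrogenase, went from 80.9 ± 37.8 to 306 ± 21.4 CPM. The 8 largest falls were in Bmp6 (-2.84 ± 0.19), a secreted ligand that regulates iron balance, Csta2 (-1.94 ± 0.13), Atp2a3 (-1.58 ± 0.18), Ifi206 (-1.54 ± 0.18), Tfrc, Taf9b (-1.40 ± 0.24), Pdk4 (-1.29 ± 0.10) and Miga1 (-1.27 ± 0.19). Bmp6 dropped from 11.6 ± 0.1502 to 1.61 ± 0.585 CPM and Pdk4, a kinase that restrains pyruvate oxidation, from 23.04 ± 1.89 to 9.38 ± 0.252 CPM.

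Of 27 measured genes of the NRF2 antioxidant list, 23 rose and 4 did not pass, with the same 23 adjusted over the list alone. The NRF2 list had a median of 0.46 (camera adjusted p = 2.32e-33, and adjusted p = 0.101 with an estimated correlation). Slc7a11, the cystine importer, rose from 96.9 ± 8.25 to 236 ± 8.59 CPM, Gclm, a subunit of the enzyme that starts glutathione synthesis, from 148 ± 6.69 to 289 ± 26.8 CPM, and Gsta4 from 21.9 ± 2.35 to 64.0 ± 4.46 CPM. Nqo1, a quinone reductase, rose from 71.7 ± 16.1 to 182 ± 1.39 CPM (log2 1.34 ± 0.10). The list of targets of the aryl hydrocarbon receptor, the sensor of polycyclic aromatic compounds, had 13 measured members, of which 5 rose and 2 fell, and 7 rose and 2 fell when adjusted over the list alone. The aryl hydrocarbon receptor list had a median of 0.29 (camera adjusted p = 0.013, and adjusted p = 0.199 with an estimated correlation). Among them Cyp1b1 rose from 6.71 ± 0.944 to 13.1 ± 1.01 CPM and Tiparp by log2 0.29 ± 0.07, while Slc7a5, an amino acid transporter, fell by log2 0.62 ± 0.06. Cyp1a1, the classical target, was near the floor at 0.414 ± 0.135 and 0.818 ± 0.459 CPM (adjusted p = 0.156). In the iron handling list of 11 genes, 3 rose and 1 fell, the same counts adjusted over the list alone, and the list was not called. The iron list had a median of 0.10 (camera adjusted p = 0.403, and adjusted p = 0.576 with an estimated correlation). Ftl1, the ferritin light chain, rose by log2 0.28 ± 0.07 (adjusted p = 0.00798; 0.0727 when the 4 EpH4 libraries were fitted alone). Of the metallothioneins, Mt1 rose by log2 0.47 ± 0.05, and Mt2 had log2 0.17 ± 0.09 (adjusted p = 0.175; 0.0317 with no filter).

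All 30 measured genes of the G2 and mitosis list rose in EpH4, also when adjusted over the list alone. The G2 and mitosis list had a median of 1.24 (camera adjusted p = 2.2e-53, and adjusted p = 0.144 with an estimated correlation). Cenpf, a kinetochore protein, rose from 9.16 ± 3.29 to 30.4 ± 0.0626 CPM, Ube2c from 7.12 ± 1.24 to 21.3 ± 1.31 CPM, and Anln from 42.7 ± 8.62 to 99.4 ± 0.568 CPM. Of 17 measured replication-dependent histone genes, 11 rose, and 13 adjusted over the list alone, such as H1f2 from 18.9 ± 1.43 to 50.9 ± 6.02 CPM. The histone list had a median of 1.43 (camera adjusted p = 4.03e-13, and adjusted p = 0.144 with an estimated correlation). Most mRNAs of these histones lack the poly(A) tail by which the libraries were selected and may share reads with near-identical copies, so their values are uncertain. In the p53 target list 18 of 23 genes rose and 2 fell, and 18 rose and 3 fell adjusted over the list alone. The p53 list had a median of 0.43 (camera adjusted p = 4.66e-14, and adjusted p = 0.144 with an estimated correlation). Mdm2, the ligase that degrades p53, went from 201 ± 1.80 to 289 ± 4.12 CPM, Ccng1 from 412 ± 19.0 to 629 ± 17.4 CPM, and Ckap2, a spindle protein, from 19.0 ± 2.15 to 40.0 ± 1.16 CPM.

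In the NF-kB cytokine and chemokine list 13 of 22 measured genes rose, and 14 rose and 1 fell when adjusted over the list alone. The NF-kB list had a median of 0.64 (camera adjusted p = 3.85e-13, and adjusted p = 0.123 with an estimated correlation). Cxcl5, a neutrophil chemokine, rose from 76.3 ± 7.18 to 226 ± 20.5 CPM, Cxcl1 (ENSMUSG00000029380, chromosome 5, 91039100 to 91040974) from 230.1 ± 30.3 to 382 ± 6.61 CPM, Ptgs2 from 726 ± 51.4 to 1403 ± 80.3 CPM and Csf3 from 12.5 ± 2.70 to 37.9 ± 3.09 CPM. Il6 rose from 6.96 ± 1.36 to 12.5 ± 2.46 CPM (adjusted p = 0.00363), a call lost without EpH4 PM2.5 replicate 2 (log2 0.62, adjusted p = 0.0590). Of 28 interferon-stimulated genes 17 rose, also adjusted over the list alone. The interferon list had a median of 0.77 (camera adjusted p = 3.96e-08, and adjusted p = 0.216 with an estimated correlation). Ifit1 went from 3.01 ± 0.776 to 9.63 ± 0.0157 CPM, while Ifi206, which lies outside the list, fell. Vim, the intermediate filament of mesenchymal cells, was at 2068 ± 29.5 and 2319 ± 100.1 CPM (adjusted p = 0.165; 0.0163 with no filter), and Cdh1, the epithelial cadherin, at 0.134 ± 0.0354 and 0.0587 ± 0.0248 CPM, too low to test. Without EpH4 PM2.5 replicate 1, 11 interferon-stimulated genes rose.

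All 13 mitochondrially encoded transcripts rose, also adjusted over the list alone, together with the mitochondrial share of counts given above. The mitochondrially encoded list had a median of 0.99 (camera adjusted p = 1.76e-29, and adjusted p = 0.144 with an estimated correlation). mt-Nd4 went from 848 ± 149 to 2000.4 ± 292 CPM and mt-Atp8 from 217 ± 3.42 to 518 ± 47.0 CPM. Of 46 ribosomal protein genes 32 fell, and 37 adjusted over the list alone. The ribosomal protein list had a median of -0.25 (camera adjusted p = 1.23e-13, and adjusted p = 0.387 with an estimated correlation). Rpl12 fell from 1619 ± 149 to 1044 ± 16.7 CPM and Rps24 from 1102 ± 80.3 to 801 ± 52.9 CPM. Their reads may be shared with near-identical copies in the genome, which was not tested. Among 26 hypoxia (HIF1) targets 3 rose and 17 fell, and 3 rose and 18 fell adjusted over the list alone. The hypoxia list had a median of -0.30 (camera adjusted p = 1.94e-09, and adjusted p = 0.245 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, fell from 981 ± 52.2 to 631 ± 43.6 CPM and P4ha1, a collagen prolyl hydroxylase, from 1216 ± 53.9 to 738 ± 45.4 CPM. Camera called 22 of 39 tested lists in this comparison, 17 up and 5 down, and with an estimated correlation 0 of 39 were called, 9 having an unadjusted p under 0.05. The count of called genes was 2451 without EpH4 untreated replicate 2, 2145 without EpH4 PM2.5 replicate 2, 2204 by the DESeq2 Wald test and 184 when tested against a 1.5-fold change. Without EpH4 untreated replicate 2 or PM2.5 replicate 2, 20 and 18 ribosomal protein genes fell.

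**Figure D1:**
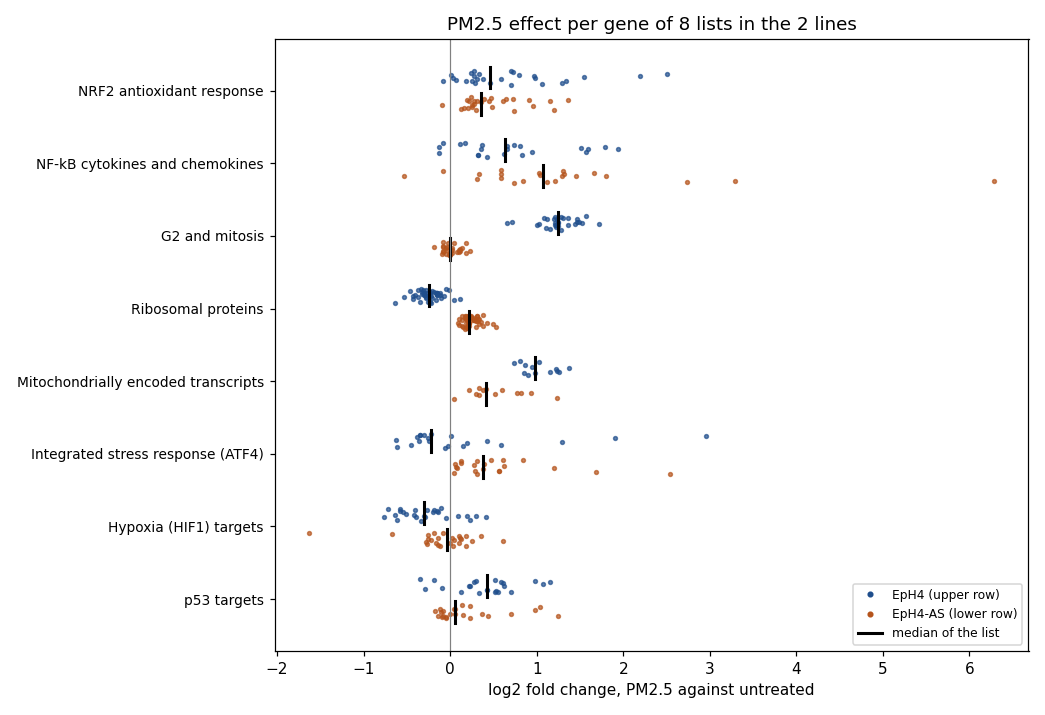
PM2.5 effect per gene of 8 lists in EpH4 (upper points, blue) and EpH4-AS (lower points, orange), as log2 fold change of PM2.5 against untreated on the horizontal axis; each point is a gene and the black bar is the list's median. The medians of the G2 and mitosis list were 1.24 in EpH4 and -0.00 in EpH4-AS, where the sign of the latter changes with the scaling of the libraries, and those of the NF-kB list 0.64 and 1.08.

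The same comparison in EpH4-AS spheroids was led by NF-kB target genes. Cxcl1, a neutrophil chemokine, rose 6.69-fold, from 20.1 ± 1.57 to 134 ± 10.7 CPM (log2 2.74 ± 0.10, adjusted p = 9.02e-10; SD, n = 2). Nfkbia, the inhibitor that NF-kB induces in feedback, rose from 183 ± 2.17 to 501 ± 5.83 CPM and Ier3, an early response gene, from 157 ± 0.825 to 534 ± 28.2 CPM. Hmox1 rose from 1226 ± 13.9 to 3161 ± 129 CPM, and Tfrc fell from 371 ± 6.03 to 74.6 ± 6.16 CPM (log2 -2.32 ± 0.11, adjusted p = 9.35e-09). Lox, the enzyme that crosslinks collagen (ENSMUSG00000024529, chromosome 18, 52649139 to 52662939), fell from 228 ± 11.6 to 73.3 ± 6.67 CPM. The test called 1529 of 13716 genes, 877 higher and 652 lower with PM2.5, of which 110 differed by more than 2-fold (90 higher, 20 lower). The 2-fold count was 59 and 63 without EpH4-AS untreated replicate 1 or 2, 81 and 70 without EpH4-AS PM2.5 replicate 1 or 2, 42 by the DESeq2 Wald test, 34 against a 1.5-fold change and 28 by limma-trend.

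By the naming rule the 8 largest rises were Cxcl1, Zc3h12a (log2 1.81 ± 0.12), Ier3 (1.77 ± 0.06), Sod2 (1.61 ± 0.10), Slpi (1.59 ± 0.28), Pcdh15 (1.58 ± 0.18), Abhd6 (1.57 ± 0.16) and Nfkbia (1.45 ± 0.05). Zc3h12a, a ribonuclease that degrades cytokine mRNAs, went from 22.2 ± 1.41 to 77.5 ± 14.2 CPM, and Sod2, the mitochondrial superoxide dismutase, from 71.3 ± 2.79 to 217 ± 20.6 CPM. The call of Slpi was lost without EpH4-AS untreated replicate 1 (log2 1.37, adjusted p = 0.0579). The 8 largest falls were Tfrc, Ptprq (-2.04 ± 0.12), Cd36 (-1.96 ± 0.09), Col3a1 (-1.95 ± 0.12), Il13ra2 (-1.70 ± 0.08), Lox (-1.63 ± 0.07), Fabp4 (-1.53 ± 0.18) and Clip4 (-1.35 ± 0.20). Il13ra2, a receptor for interleukin 13, dropped from 363 ± 19.7 to 112 ± 16.6 CPM and Col3a1, a fibrillar collagen, from 45.1 ± 0.262 to 11.6 ± 1.75 CPM.

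In the NF-kB list 14 of 22 measured genes rose, and 15 adjusted over the list alone; this was the 1 camera call of the 5 comparisons that held with an estimated correlation. The NF-kB list had a median of 1.08 (camera adjusted p = 4.56e-57, and adjusted p = 0.0276 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, went from 70.4 ± 3.53 to 144 ± 0.646 CPM and the adhesion molecule Icam1 from 61.9 ± 4.13 to 127 ± 1.37 CPM, whereas Il6 was at 0.370 ± 0.0129 and 0.246 ± 0.266 CPM (adjusted p = 0.745). Among 23 immediate early genes 9 rose, and 10 rose and 4 fell adjusted over the list alone, including Zfp36 from 48.7 ± 0.0525 to 90.7 ± 6.27 CPM and Junb from 164 ± 3.63 to 237 ± 0.458 CPM. The immediate early list had a median of 0.09 (camera adjusted p = 4.66e-09, and adjusted p = 0.0516 with an estimated correlation). In the NRF2 list 19 of 27 genes rose, and 23 adjusted over the list alone. The NRF2 list had a median of 0.36 (camera adjusted p = 1.63e-29, and adjusted p = 0.0516 with an estimated correlation). Slc7a11 went from 15.5 ± 1.89 to 35.6 ± 2.02 CPM, Gclm from 65.8 ± 0.806 to 128 ± 0.920 CPM and Gstp1 from 147 ± 1.85 to 226 ± 2.15 CPM. Nqo1 rose from 6.21 ± 0.608 to 10.4 ± 0.252 CPM (adjusted p = 0.0286). Without EpH4-AS untreated replicate 1 or 2, or PM2.5 replicate 1 or 2, the adjusted p of Nqo1 was 0.204, 0.105, 0.0976 and 0.1001. In these 4 fits 10, 12, 15 and 12 genes of the NRF2 list and 5, 4, 7 and 7 immediate early genes rose, and 12 NF-kB genes rose in each.

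Of 21 genes of the ATF4-driven integrated stress response 13 rose, also adjusted over the list alone, such as Ddit4 from 90.1 ± 1.87 to 137 ± 5.62 CPM, Mthfd2 from 129 ± 1.74 to 191 ± 2.69 CPM and Chac1 from 16.8 ± 0.681 to 26.0 ± 0.0655 CPM. The ATF4 list had a median of 0.38 (camera adjusted p = 4.59e-16, and adjusted p = 0.251 with an estimated correlation). Ribosomal protein genes rose, 26 of 46 and 39 adjusted over the list alone, for example Rpl15 from 236 ± 4.65 to 341 ± 2.16 CPM and Rplp0 from 325 ± 7.10 to 438 ± 5.29 CPM. The ribosomal protein list had a median of 0.22 (camera adjusted p = 1.05e-19, and adjusted p = 0.326 with an estimated correlation). Of 13 mitochondrially encoded transcripts 8 rose, and 9 adjusted over the list alone, at the low mitochondrial share of this line. The mitochondrially encoded list had a median of 0.42 (camera adjusted p = 1.39e-09, and adjusted p = 0.326 with an estimated correlation). mt-Nd2 went from 16.4 ± 0.875 to 31.4 ± 1.25 CPM and mt-Cytb from 67.5 ± 8.71 to 115 ± 2.17 CPM. In the adipocyte marker list 4 of 5 genes fell, also adjusted over the list alone. The adipocyte list had a median of -0.36 (camera adjusted p = 6.98e-15, and adjusted p = 0.0516 with an estimated correlation). Cd36, a fatty acid transporter, fell from 49.9 ± 0.427 to 12.8 ± 0.934 CPM and Fabp4, a fatty acid carrier, from 15.4 ± 2.12 to 5.33 ± 0.710 CPM. Of 19 TGF-beta targets 7 rose and 1 fell, the same counts adjusted over the list alone, among them Ccn2 from 18.7 ± 2.10 to 40.9 ± 9.64 CPM. The TGF-beta list had a median of 0.13 (camera adjusted p = 0.00217, and adjusted p = 0.326 with an estimated correlation). Without EpH4-AS untreated replicate 1 or 2, or PM2.5 replicate 1 or 2, the ATF4 list had 7, 7, 12 and 9 called rises, the ribosomal protein list 5, 4, 11 and 11, the mitochondrially encoded list 2, 4, 5 and 3 and the TGF-beta list 4, 3, 4 and 4. The adipocyte list had 2, 2, 4 and 3 called falls in these fits. Pparg (log2 -0.36) lost its call without untreated replicate 1 (adjusted p = 0.0803) or 2 (0.0501), and Lpl (-0.27) without untreated replicate 1 (0.117) or 2 (0.0601) or PM2.5 replicate 2 (0.0666).

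No gene of the G2 and mitosis list was called in EpH4-AS: edgeR called 0 of 30, with 0 at an unadjusted p under 0.05, and DESeq2 and limma-trend called 0 each. With the 4 EpH4-AS libraries fitted alone 2 were called, Cenpf (log2 -0.19, adjusted p = 0.00959) and Kif20a (0.18, adjusted p = 0.0225). The median was -0.00, with a sign that changes with the scaling and differs from that of the mean (camera adjusted p = 0.898, and adjusted p = 0.986 with an estimated correlation). Cenpf was at 106 ± 7.19 and 92.8 ± 1.502 CPM (adjusted p = 0.303; 0.0332 and 0.0293 without EpH4 untreated replicate 1 or 2) and Birc5 at 27.3 ± 1.45 and 30.8 ± 2.44 CPM. Of 13 aryl hydrocarbon receptor targets 2 rose, and 3 adjusted over the list alone. The aryl hydrocarbon receptor list had a median of 0.31 (camera adjusted p = 0.00685, and adjusted p = 0.236 with an estimated correlation). Ereg, a growth factor, rose from 7.90 ± 0.187 to 13.2 ± 1.19 CPM. Cyp1b1 was at 0.373 ± 0.187 and 0.993 ± 0.329 CPM (adjusted p = 0.0785, and 0.0230 with no filter, 0.0482 with the 4 EpH4-AS libraries fitted alone and 0.0493 without EpH4 untreated replicate 1), Tiparp at 293 ± 14.8 and 297 ± 29.3 CPM (adjusted p = 0.899), and Cyp1a1 had 0 counts untreated and 2 with PM2.5. In the iron handling list 5 of 11 genes rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone. The iron list had a median of 0.26 (camera adjusted p = 0.0409, and adjusted p = 0.326 with an estimated correlation). That call was lost with DESeq2 size factors (adjusted p = 0.0509) and without EpH4-AS PM2.5 replicate 2 (adjusted p = 0.0585). Ftl1 rose from 91.8 ± 8.82 to 144 ± 11.2 CPM, Mt1 from 13.8 ± 0.743 to 21.6 ± 2.04 CPM and Mt2 from 26.5 ± 4.59 to 47.8 ± 6.07 CPM. Vim was at 3653 ± 207 and 4285 ± 597 CPM (adjusted p = 0.0939, and 0.0398 by DESeq2, 0.0143 with these 4 libraries fitted alone, 0.000149 with no filter, 0.0191 without EpH4-AS PM2.5 replicate 1 and 0.0497 without EpH4 untreated replicate 1), and Cdh1 at 0.0316 ± 0.0447 and 0.0563 ± 0.00288 CPM. Without any 1 of the 4 EpH4-AS libraries, 2 iron genes rose and 1 fell, and 1 aryl hydrocarbon receptor target rose, against 4 without EpH4 untreated replicate 1.

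Camera called 21 of 39 lists in EpH4-AS, 18 up and 3 down, and 1 with an estimated correlation, 7 having an unadjusted p under 0.05. The number of called genes in EpH4-AS depended on the libraries fitted: it was 363 and 372 without EpH4-AS untreated replicate 1 or 2, and 695 and 490 without EpH4-AS PM2.5 replicate 1 or 2. It was 2088 and 2079 without EpH4 untreated replicate 1 or 2, 2995 when the 4 EpH4-AS libraries were fitted alone, 1004 by the DESeq2 Wald test and 40 against a 1.5-fold change. The direction of the excess also depended on the scaling: with library totals 715 genes were higher and 916 lower, and limma-trend on the authors' RPKM called 698 higher and 866 lower.

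**Figure D2:**
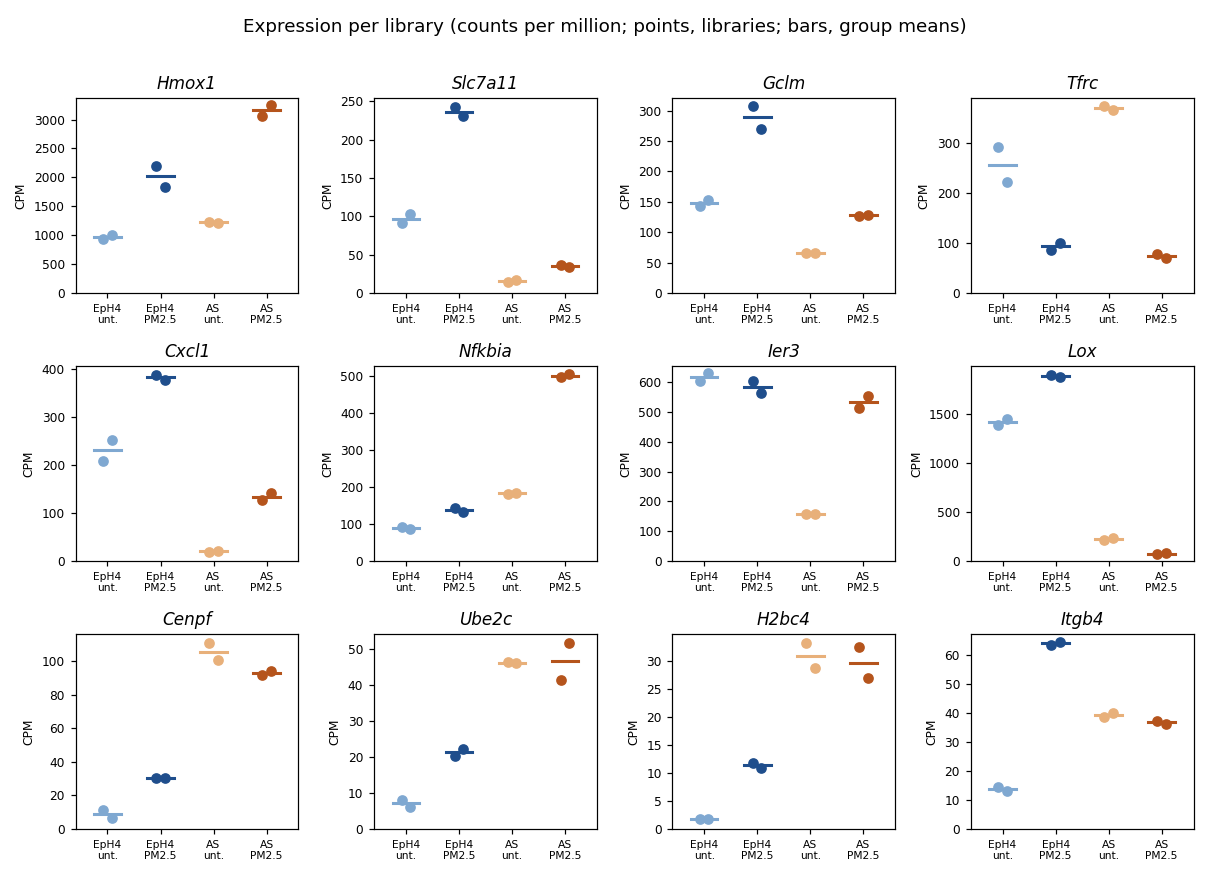
CPM of 12 genes in each library (points) with the group means (bars), for EpH4 and EpH4-AS without and with PM2.5. Hmox1 and Slc7a11 were higher and Tfrc lower with PM2.5 in both lines, Cenpf stood at 9.16 and 30.4 CPM in EpH4 and at 106 and 92.8 CPM in EpH4-AS, and Cxcl1 at 230.1 and 382 CPM and at 20.1 and 134 CPM.

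The difference between the 2 PM2.5 effects, EpH4-AS minus EpH4, was tested as the interaction that the design names. Itgb4 rose in EpH4 and was at 39.2 ± 0.971 and 36.7 ± 0.841 CPM in EpH4-AS without and with PM2.5, a difference of log2 -2.32 ± 0.10 (adjusted p = 1.31e-08). Ier3 was at 618 ± 17.2 and 585 ± 28.1 CPM in EpH4 and rose in EpH4-AS (difference 1.85 ± 0.08, adjusted p = 1.31e-08). Lox was at 1419.6 ± 43.6 CPM in untreated EpH4 and 1892 ± 9.61 CPM with PM2.5, and fell in EpH4-AS (difference -2.05 ± 0.09, adjusted p = 1.53e-08). Cxcl1 rose in both lines, with a larger effect in EpH4-AS by log2 2.01 ± 0.13. The test called 1932 genes, 1042 with the more positive effect in EpH4-AS and 890 with the more positive effect in EpH4.

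The other genes among the 10 with the smallest p were H2bc4 (log2 difference -2.73 ± 0.20), Cdk2ap2 (1.06 ± 0.08), Jag1 (1.18 ± 0.10), Sqstm1 (0.96 ± 0.08), Plod1 (1.14 ± 0.10) and Mgst1 (-1.04 ± 0.09). Sqstm1, the autophagy receptor p62, was at 1500.2 ± 62.9 and 1399 ± 54.1 CPM in EpH4 and at 232 ± 8.63 and 421 ± 15.2 CPM in EpH4-AS. Jag1, a Notch ligand, was at 37.9 ± 0.981 and 34.4 ± 2.62 CPM in EpH4 and at 30.4 ± 1.56 and 62.5 ± 2.41 CPM in EpH4-AS. Plod1, a collagen lysyl hydroxylase, was at 574 ± 16.1 and 301 ± 31.7 CPM in EpH4 and at 599 ± 16.5 and 689.8 ± 47.7 CPM in EpH4-AS.

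In the G2 and mitosis list 29 of 30 genes had a more negative effect in EpH4-AS, and 30 adjusted over the list alone, with Cenpf at log2 -1.91 ± 0.18 and Ube2c at -1.55 ± 0.16. The G2 and mitosis list had a median difference of -1.19 (camera adjusted p = 7.73e-49, and adjusted p = 0.297 with an estimated correlation). Of 28 S phase and DNA replication genes 13 had a more negative effect, and 16 adjusted over the list alone, for example Rrm2, a ribonucleotide reductase subunit, at -1.17 ± 0.21. The S phase list had a median of -0.37 (camera adjusted p = 1.59e-08, and adjusted p = 0.416 with an estimated correlation). Of 17 histone genes 6 did, the same number adjusted over the list alone, with H1f2 at -1.30 ± 0.15. The histone list had a median of -0.66 (camera adjusted p = 5.63e-05, and adjusted p = 0.36 with an estimated correlation). Ribosomal protein genes had a more positive effect in EpH4-AS in 41 of 46, and 45 adjusted over the list alone, with Rpl12 at 0.94 ± 0.10. The ribosomal protein list had a median of 0.49 (camera adjusted p = 1.47e-40, and adjusted p = 0.316 with an estimated correlation). The ATF4 list had 15 of 21 genes with a more positive effect, also adjusted over the list alone. The ATF4 list had a median of 0.51 (camera adjusted p = 5.6e-15, and adjusted p = 0.316 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, was at 129 ± 4.69 and 110.1 ± 6.96 CPM in EpH4 against its rise in EpH4-AS, and Nupr1, a stress-induced nuclear protein, at 144 ± 10.4 and 93.7 ± 7.99 CPM in EpH4 and 31.2 ± 0.136 and 43.4 ± 1.58 CPM in EpH4-AS. The effect of PM2.5 on the ATF4 list within EpH4 was called down, with 3 genes higher and 11 lower, and 4 and 11 adjusted over the list alone. The ATF4 list had a median of -0.23, but a mean of 0.16 (camera adjusted p = 0.0483, and adjusted p = 0.583 with an estimated correlation). Without EpH4-AS untreated replicate 1 or 2, or PM2.5 replicate 1 or 2, the more negative effects numbered 5, 5, 5 and 12 in the S phase list and 3 in each fit in the histone list. They were 8 and 6 for S phase without EpH4 untreated or PM2.5 replicate 2, and 3 for histones without EpH4 PM2.5 replicate 1.

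Of 17 unfolded protein response genes 13 had a more positive effect in EpH4-AS, and 15 adjusted over the list alone. The unfolded protein list had a median of 0.41 (camera adjusted p = 1.29e-12, and adjusted p = 0.36 with an estimated correlation). Dnajb9, a chaperone of the endoplasmic reticulum, was at 128 ± 2.40 and 71.1 ± 9.25 CPM in EpH4 and at 30.8 ± 3.34 and 34.3 ± 1.99 CPM in EpH4-AS. In the NF-kB list 9 of 22 genes had a more positive and 1 a more negative effect in EpH4-AS, the same counts adjusted over the list alone. The NF-kB list had a median of 0.56 (camera adjusted p = 1.9e-08, and adjusted p = 0.297 with an estimated correlation). Lif, a cytokine of the interleukin 6 family, was at 294 ± 13.7 and 317 ± 31.2 CPM in EpH4 and at 43.2 ± 1.20 and 99.969 ± 9.09 CPM in EpH4-AS. Of 13 mitochondrially encoded transcripts 7 had a more negative effect, and 10 adjusted over the list alone. The mitochondrially encoded list had a median of -0.51 (camera adjusted p = 1.43e-05, and adjusted p = 0.416 with an estimated correlation). mt-Nd5 differed by log2 -0.61 ± 0.14 (adjusted p = 0.0114), a call lost without EpH4-AS untreated replicate 1 (0.0663), EpH4-AS untreated replicate 2 (0.0790) or EpH4-AS PM2.5 replicate 1 (0.0627). For Hmox1 the difference was log2 0.30 ± 0.11 (adjusted p = 0.08; 0.0249 without EpH4 untreated replicate 1 and 0.00591 without EpH4 PM2.5 replicate 1). For Nqo1 it was -0.60 ± 0.23 (adjusted p = 0.101; 0.000198 without EpH4 untreated replicate 1), and for Tiparp -0.27 ± 0.10 (adjusted p = 0.0814; 0.0242 without EpH4 untreated replicate 2). Mt2 had a larger effect in EpH4-AS (0.69 ± 0.14, adjusted p = 0.00599; 0.0626 without EpH4-AS untreated replicate 1 and 0.0545 by limma-trend on RPKM). The adjusted p was 0.307 for Mt1, 0.626 for Cyp1b1, 0.541 for Cyp1a1, 0.315 for Il6 and 0.776 for Vim. By limma-trend on RPKM the difference was called for Il6 (log2 -0.71, adjusted p = 0.0459), Nqo1 (adjusted p = 0.0400) and, with the sign reversed, Cyp1b1 (-0.43, adjusted p = 0.0297). DESeq2 called it for Nqo1 (adjusted p = 0.0343) and Hmox1 (0.0308), library totals for Tiparp (0.0446), and the fit with no filter for Nqo1 (0.00121), Hmox1 (0.000243) and Tiparp (0.0125). The more positive effects in the unfolded protein list numbered 7 without EpH4-AS untreated replicate 2 and 8 without EpH4-AS PM2.5 replicate 1. The more negative ones in the mitochondrially encoded list were 2, 0, 0 and 3 without EpH4-AS untreated replicate 1 or 2, or PM2.5 replicate 1 or 2, and 3 without EpH4 PM2.5 replicate 2.

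Across all 13716 genes the log2 effects of PM2.5 in the 2 lines correlated with Pearson's r = 0.0557 and Spearman's rho = 0.0990; genes are not independent replicates. Over the 8856 genes at 5 CPM or more in both lines r was 0.143 and rho 0.109. Called genes overlapped by 223 higher in both lines against 125 for independent lists, and by 155 lower in both against 84.1. Of 595 genes called in both lines 378 went the same way, among them Hmox1, Slc7a11, Gclm and Tfrc, and 217 the opposite way. Of 3131 genes called in EpH4 and not in EpH4-AS, the difference itself was called for 1107, and of 934 called in EpH4-AS and not in EpH4 for 413. Without EpH4-AS untreated replicate 1 or 2, or PM2.5 replicate 1 or 2, the genes called in both lines numbered 147, 147, 278 and 209. Of these 82, 90, 146 and 105 were higher in both, 22, 19, 60 and 32 lower in both and 43, 38, 72 and 72 went the opposite way, and the 4 genes named here went the same way in each fit. In these fits 216, 225, 417 and 281 genes were called in EpH4-AS alone, with the difference called for 107, 115, 202 and 149, and for 606, 620, 733 and 856 of those called in EpH4 alone. Without EpH4 untreated replicate 2 or EpH4 PM2.5 replicate 2, 1868 and 1702 genes were called in EpH4 alone, with the difference called for 673 and 615, and 1496 and 1234 in EpH4-AS alone. The genes called in both lines were 864 without EpH4 untreated replicate 1, with 352 of them opposite. Camera called 20 of 39 lists for the interaction, 8 up and 12 down, and 0 of 39 with an estimated correlation, 5 having an unadjusted p under 0.05. The count of 1932 genes became 875 and 884 without EpH4-AS untreated replicate 1 or 2, 1141 and 1246 without EpH4-AS PM2.5 replicate 1 or 2, 1259 by the DESeq2 Wald test and 66 against a 1.5-fold change, and with library totals the split was 838 higher and 1100 lower.

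The comparison of untreated EpH4-AS with untreated EpH4 addressed malignant transformation. Pparg, the regulator of fat cell genes (ENSMUSG00000000440, chromosome 6, 115337912 to 115467360), was higher in EpH4-AS at 256 ± 4.23 CPM against 2.77 ± 0.200 CPM in EpH4 (SD, n = 2; log2 6.53 ± 0.10, adjusted p = 2.26e-16). Col1a2, a collagen I chain (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544), was lower at 34.4 ± 2.99 against 1067 ± 86.9 CPM (log2 -4.95 ± 0.10). Of the gene lists, 27 of 30 mitosis genes were higher and 1 lower in EpH4-AS. Lower were 13 of 13 mitochondrially encoded, 42 of 46 ribosomal protein, 19 of 23 p53 target and 19 of 26 hypoxia genes, while 3, 2 and 6 of the last 3 lists were higher. With an estimated correlation the adjusted p of these 5 lists ranged from 0.502 to 0.835. The test called 12238 of 13716 genes, 5976 higher and 6262 lower in EpH4-AS, of which 7566 differed by more than 2-fold (3308 higher, 4258 lower), or 5028 by limma-trend. The direction of the excess depended on the scaling, with 6145 higher and 6088 lower by library totals and 6567 and 5552 by limma-trend on RPKM. Along with these genes the share of reads outside exons, the mitochondrial share and the number of genes with a count differed between the lines, the last at 16568.5 ± 95.5 in untreated EpH4 and 14801 ± 56.6 in untreated EpH4-AS (SD, n = 2). Over the 2918 genes with about the same level in both lines, 3.17% of gene reads lay outside exons in EpH4-AS against 12.4% in EpH4, and the share was lower in EpH4-AS for 96.3% of them. Whether the reads of both lines come from cells of the same strain and origin was not established, and the line comparisons rest on the labels in this.

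The 8 genes highest in EpH4-AS by the naming rule had 0 counts in untreated EpH4, so that each difference is a lower bound set by 3 counts over the group. Slc45a1 (319.5 ± 2.26 CPM in EpH4-AS) was at least 5608-fold higher, Vldlr, a lipoprotein receptor, at least 4775-fold, Ctsf at least 2396-fold, Iqgap2 at least 2383.5-fold, Efemp1 at least 2098-fold and Ubash3b at least 2059-fold. Aldoart1 and Aldoart2, retrogene copies of an aldolase gene, were at least 2839.9-fold and 2972-fold higher, and their reads may be shared with near-identical copies. Lower in EpH4-AS were Mgp, an inhibitor of calcification (at least 1355.5-fold), Zfp968 (at least 930.2-fold), Csta2 (at least 174-fold), Ppargc1a, a regulator of mitochondrial biogenesis (at least 124-fold), H2ac18 (at least 98.1-fold), Steap4 (at least 97.3-fold) and Ifi206 (at least 96.7-fold), all with 0 counts in untreated EpH4-AS. Il33, an alarmin cytokine, had 9566 counts in EpH4 and 3 in EpH4-AS, a ratio of 1963 (95% counting interval 672 to 9523). These bounds and intervals cover counting error only.

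All 13 mitochondrially encoded transcripts were lower in EpH4-AS, with mt-Cytb at 67.5 ± 8.71 against 1671 ± 250.0 CPM and mt-Nd2 at 16.4 ± 0.875 against 544 ± 74.5 CPM. The drop was uneven, from 2.04-fold for mt-Nd1 (359 ± 29.8 against 734 ± 206 CPM) to 57.9-fold for mt-Nd4l (2.01 ± 0.463 against 117 ± 24.6 CPM). The cause of this unevenness was not tested. The mitochondrially encoded list had a median of -3.86 (camera adjusted p = 1.5e-09, and adjusted p = 0.502 with an estimated correlation). In this comparison the counts within each list were the same when adjusted over the list alone. Of 46 ribosomal protein genes 42 were lower and 3 higher, with Rpl7 at 96.5 ± 0.955 against 1519.7 ± 80.4 CPM and Rps6 at 250.1 ± 9.84 against 2399.8 ± 149.6 CPM. The ribosomal protein list had a median of -1.44 (camera adjusted p = 1.52e-12, and adjusted p = 0.631 with an estimated correlation). Of 23 p53 targets 19 were lower and 2 higher, such as Cdkn1a, the cell cycle inhibitor p21, at 55.3 ± 3.76 against 572 ± 16.7 CPM, and the death receptor gene Tnfrsf10b at 3.83 ± 0.133 against 73.0 ± 3.69 CPM. The p53 list had a median of -1.82 (camera adjusted p = 6.54e-07, and adjusted p = 0.502 with an estimated correlation). Among 26 hypoxia targets 19 were lower and 6 higher, with Car9, a carbonic anhydrase, at 10.8 ± 0.0690 against 294 ± 26.3 CPM and Ldha at 232 ± 2.74 against 2437 ± 40.2 CPM. The hypoxia list had a median of -1.02 (camera adjusted p = 1.03e-05, and adjusted p = 0.591 with an estimated correlation). In the G2 and mitosis list 27 of 30 genes were higher and 1 lower, with Plk1, a mitotic kinase, at 83.0 ± 0.792 against 6.58 ± 2.78 CPM and Cenpf at 106 ± 7.19 against 9.16 ± 3.29 CPM. The G2 and mitosis list had a median of 1.87 (camera adjusted p = 0.000347, and adjusted p = 0.835 with an estimated correlation). Of 10 adipocyte markers, the 5 that passed the filter on low counts were all higher. At 1 CPM or more were 5 markers in untreated EpH4-AS and 2 in untreated EpH4. The filter keeps genes expressed in either line, so this shared direction does not describe the members too low to test. The adipocyte list had a median of 6.53 (camera adjusted p = 2e-08, and adjusted p = 0.502 with an estimated correlation). Lpl, lipoprotein lipase, was at 1081 ± 23.6 against 165 ± 2.97 CPM, and Cd36 had 1618 counts against 3 (ratio 876, 95% counting interval 299 to 4252).

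In the NF-kB list 15 of 22 genes were lower and 5 higher. The NF-kB list had a median of -2.82, or -2.76 with the gene at 0 counts at its bound (camera adjusted p = 0.0116, and adjusted p = 0.502 with an estimated correlation). Lcn2, an iron-binding acute phase protein, was at 19.0 ± 2.75 against 1821 ± 192 CPM, Cxcl1 at 20.1 ± 1.57 against 230.1 ± 30.3 CPM and Il6 at 0.370 ± 0.0129 against 6.96 ± 1.36 CPM, while Icam1 was higher at 61.9 ± 4.13 against 0.0778 ± 0.0587 CPM. Of 8 metal response genes 6 were lower and 2 higher, a call lost without EpH4 untreated replicate 1 or 2 (adjusted p = 0.0648 and 0.0684), with Mt1 at 13.8 ± 0.743 against 255 ± 5.98 CPM and Mt2 at 26.5 ± 4.59 against 612 ± 3.81 CPM. The metal response list had a median of -2.53 (camera adjusted p = 0.0136, and adjusted p = 0.502 with an estimated correlation). Hmox1 was higher in EpH4-AS (log2 0.34 ± 0.08), Nqo1 (-3.53 ± 0.15) and Cyp1b1 (-4.16 ± 0.31) were lower, and Cyp1a1 had 22 counts in EpH4 and 0 in EpH4-AS, at least 4.52-fold lower. Tiparp was at 293 ± 14.8 against 254 ± 17.7 CPM (adjusted p = 0.0116; 0.104 without EpH4 untreated replicate 1 and 0.173 without EpH4-AS untreated replicate 1).

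Markers of epithelial cells were low in both lines. The median of 37 epithelial junction and adhesion genes was 0.134 CPM in untreated EpH4 and 0.185 CPM in untreated EpH4-AS, with 11 and 13 of them at 1 CPM or more. Cdh1, the epithelial cadherin, had 7 counts in untreated EpH4 and 1 in untreated EpH4-AS, a ratio of 4.31 (95% counting interval 0.554 to 194). Among the 20 tested members 12 were higher and 7 lower in EpH4-AS, with Dsp, a desmosome protein, at 37.3 ± 0.579 against 0.321 ± 0.0602 CPM and F11r, a tight junction protein, at 1.94 ± 0.325 against 75.2 ± 0.277 CPM. The epithelial junction list had a median of 0.91 (camera adjusted p = 0.767, and adjusted p = 0.926 with an estimated correlation). Of 14 tested luminal mammary markers 5 were higher and 8 lower, with Cd24a at 1.17 ± 0.308 against 80.4 ± 2.18 CPM and Areg at 18.2 ± 0.764 against 84.8 ± 3.32 CPM. The luminal list had a median of -1.26 (camera adjusted p = 0.0728, and adjusted p = 0.502 with an estimated correlation). Genes of the mesenchymal list were abundant, with 17 of 36 higher and 17 lower in EpH4-AS. The mesenchymal list had a median of 0.44 (camera adjusted p = 0.987, and adjusted p = 0.996 with an estimated correlation). Vim was at 3653 ± 207 against 2068 ± 29.5 CPM, Cdh2, the neural cadherin, at 5.04 ± 0.480 against 146 ± 0.469 CPM, and Lox at 228 ± 11.6 against 1419.6 ± 43.6 CPM. Of 15 fibroblast markers 12 were lower and 2 higher, with Pdgfra at 59.2 ± 1.43 against 362 ± 0.298 CPM and the complement gene C3 at 36.4 ± 1.05 against 748 ± 94.9 CPM. The fibroblast list had a median of -2.61, or -2.57 with the gene at 0 counts at its bound (camera adjusted p = 0.0105, and adjusted p = 0.502 with an estimated correlation). Of 18 macrophage and leukocyte markers, the 5 that passed the filter were all lower, with Cd68, a lysosomal protein, at 38.3 ± 1.20 against 172 ± 0.157 CPM. At 1 CPM or more were 4 markers in untreated EpH4 and 2 in untreated EpH4-AS. The shared direction does not describe the members too low to test. The macrophage list had a median of -3.98, or -2.52 with the gene at 0 counts at its bound (camera adjusted p = 0.0901, and adjusted p = 0.707 with an estimated correlation). Camera called 12 of 39 lists, 2 up and 10 down, and 0 with an estimated correlation, 2 having an unadjusted p under 0.05.

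**Figure D3:**
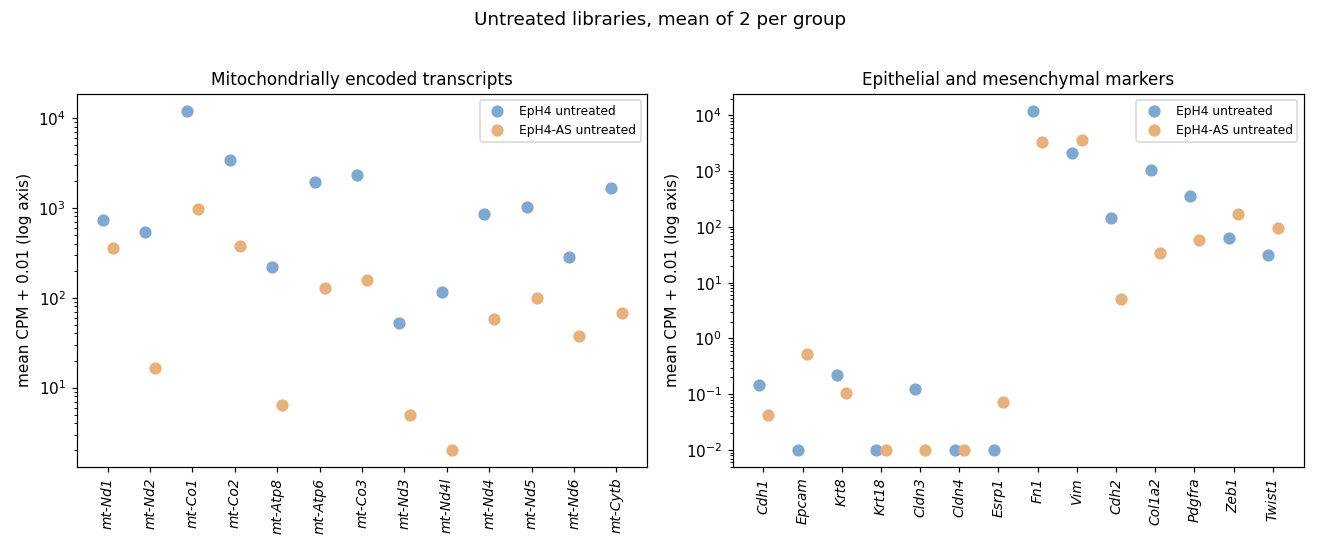
Mean CPM + 0.01 of untreated libraries (n = 2, log axis) in EpH4 (blue) and EpH4-AS (orange), for the 13 mitochondrially encoded transcripts on the left and for markers of epithelial and mesenchymal cells on the right. mt-Cytb stood at 1671 and 67.5 CPM, Cdh1 at 0.134 and 0.0316 CPM and Vim at 2068 and 3653 CPM.

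With PM2.5 in both lines, the comparison of EpH4-AS with EpH4 called 12211 genes, 5970 higher and 6241 lower. By limma-trend on RPKM the excess turned, with 6504 higher and 5653 lower, while library totals gave 6033 higher and 6167 lower. Fkbp10, a collagen chaperone at 450.2 ± 26.4 CPM in EpH4-AS with PM2.5, was at least 7578-fold higher, Pygl, a glycogen phosphorylase, at least 4329-fold, Eml2 at least 3979-fold, the retrogene Aldoart2 at least 3035-fold and Ctsf at least 2099-fold, each with 0 counts in exposed EpH4. Lower in EpH4-AS, with 0 counts there, were Mgp (at least 1651-fold), Steap4 (at least 145-fold), Lmcd1 (at least 136-fold), Gdpd2 (at least 129-fold) and Tns4 (at least 110.1-fold). All 13 mitochondrially encoded transcripts were lower, with mt-Atp8 at 11.2 ± 0.650 against 518 ± 47.0 CPM. Here too the log2 differences were uneven, from -1.94 for mt-Nd1 to -5.85 for mt-Nd4l. The mitochondrially encoded list had a median of -4.28 (camera adjusted p = 6.6e-12, and adjusted p = 0.506 with an estimated correlation). Of 23 p53 targets 21 were lower and 1 higher, with Ccng1 at 58.7 ± 0.176 against 629 ± 17.4 CPM. The p53 list had a median of -2.25 (camera adjusted p = 2.98e-09, and adjusted p = 0.422 with an estimated correlation). Of 46 ribosomal protein genes 34 were lower and 8 higher. The ribosomal protein list had a median of -0.94 (camera adjusted p = 2.25e-06, and adjusted p = 0.756 with an estimated correlation). Interferon-stimulated genes were lower in 20 of 28 and higher in 6, with Ifit2 at 0.674 ± 0.0451 against 37.4 ± 3.85 CPM and Mx2 at 25.9 ± 1.80 against 0.399 ± 0.133 CPM. The interferon list had a median of -2.22 (camera adjusted p = 0.13, and adjusted p = 0.756 with an estimated correlation). In the G2 and mitosis list 20 of 30 genes were higher and 4 lower, and the list was called without EpH4 untreated replicate 1 or 2 (adjusted p = 0.0241 and 0.0229). The G2 and mitosis list had a median of 0.63 (camera adjusted p = 0.253, and adjusted p = 0.931 with an estimated correlation).

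Between the exposed lines Plk1 was at 89.5 ± 8.91 against 15.8 ± 0.301 CPM, and Cenpa, the centromeric histone, at 0.870 ± 0.0749 against 13.8 ± 0.519 CPM. Hmox1 (log2 0.65 ± 0.08) and Vim (0.89 ± 0.08) were higher in EpH4-AS, and Nqo1 (-4.13 ± 0.13), Mt1 (-4.03 ± 0.07), Mt2 (-3.84 ± 0.10), Il6 (-5.59 ± 0.36), Cxcl1 (-1.51 ± 0.08) and Cyp1b1 (-3.73 ± 0.22) were lower. Cyp1a1 had 42 counts in exposed EpH4 and 2 in exposed EpH4-AS, a ratio of 14.8 (95% counting interval 3.84 to 126), and Tiparp had log2 -0.06 ± 0.07 (adjusted p = 0.383). Camera called 7 of 39 lists, 1 up and 6 down, and 0 with an estimated correlation, 3 having an unadjusted p under 0.05. In this comparison too, the counts within each list were the same when adjusted over the list alone.

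The effect of PM2.5 in EpH4 was also set beside the difference between the untreated lines. Across genes the 2 sets of log2 fold changes had Pearson's r = 0.0754, Spearman's rho = 0.0375 and a covariance of 0.139. Without EpH4 untreated replicate 1 or 2 r was 0.169 and 0.144, and without EpH4 PM2.5 replicate 1 or 2 it was 0.0260 and 0.0218. Genes lower with PM2.5 and lower in EpH4-AS numbered 1036 against 808 for independent lists, genes higher in both 873 against 852, higher with PM2.5 and lower in EpH4-AS 883 against 893, and lower with PM2.5 and higher in EpH4-AS 570 against 771. In the same order these were 679, 533, 622 and 351 without EpH4 untreated replicate 2, and 576, 541, 535 and 284 without EpH4 PM2.5 replicate 2, against 511, 562, 583 and 492, and 430.3, 523, 547 and 411 for independent lists. Both comparisons share the 2 untreated EpH4 libraries, so part of this excess may come from them. With 1 of the 2 given to each comparison, r was 0.0638 with replicate 1 and 0.0571 with replicate 2 on the PM2.5 side. The like fits, in which both comparisons shared 1 untreated library, are those above with r of 0.169 and 0.144. So r was lower where that library was not shared. The overlaps were not counted again with the libraries divided. In 20 simulations of unchanged groups against shared controls r was 0.457 ± 0.0250 and the covariance 0.0154 ± 0.00151 (SD). These simulations gave all libraries the untreated EpH4 means and so held no difference between the lines. Their r is therefore not comparable with the observed r.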

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

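Among the tests in this part, that of a general damping of changes in EpH4-AS and the fit without mitochondrially encoded genes were chosen after the result was seen. Each result here was singled out because the interaction test called a difference between the PM2.5 effects in EpH4-AS and EpH4, with n = 2 libraries per group.

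The difference was called for 1932 of 13716 tested genes (14.1%), and for 64 of the 100 genes named in the PM2.5 comparisons of the lines. Many of these 100 were named for a large effect or a small p in 1 line of the same data. Their selection favours a called difference, so the 2 shares are not comparable. Among the 10 genes with the smallest p, the log2 difference, EpH4-AS minus EpH4, was 2.01 for the chemokine Cxcl1, 1.85 for Ier3, 1.18 for the Notch ligand Jag1, 1.14 for Plod1, 1.06 for Cdk2ap2 and 0.96 for Sqstm1. It was -2.73 for the histone gene H2bc4, -2.32 for the integrin Itgb4, -2.05 for Lox and -1.04 for the glutathione transferase Mgst1. Mt2 differed by 0.69, a call lost without EpH4-AS untreated replicate 1 (adjusted p = 0.0626).

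Of gene lists, 20 were called for the difference by camera and 0 with an estimated correlation. The median log2 difference was positive for NF-kB cytokines and chemokines (0.56), the ATF4 stress response (0.51), ribosomal proteins (0.49), the unfolded protein response (0.41), hypoxia targets (0.31), glycolysis (0.19), immediate early genes (0.14) and lysosome and autophagy genes (0.11). It was negative for G2 and mitosis (-1.19), histones (-0.66), interferon-stimulated genes (-0.52), mitochondrially encoded transcripts (-0.51), basal and myoepithelial markers (-0.40), S phase (-0.37), YAP/TEAD targets (-0.29), basement membrane (-0.27), fatty acid synthesis (-0.25), cholesterol biosynthesis (-0.20), p53 targets (-0.18) and mesenchymal genes (-0.14).

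Mitosis genes rose with PM2.5 in EpH4, and none was called in EpH4-AS by edgeR (0 of 30 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-trend). With the EpH4-AS libraries fitted alone Cenpf (log2 -0.19, adjusted p = 0.00959) and Kif20a (0.18, adjusted p = 0.0225) were called, and Cenpf also without EpH4 untreated replicate 1 or 2 (adjusted p = 0.0332 and 0.0293). A single EpH4 library as the only source of the rise is argued against, as the list's median stayed positive without each in turn. The median was 1.60 and 0.95 without untreated replicate 1 or 2, and 1.25 and 1.24 without PM2.5 replicate 1 or 2. The size of the rise therefore depended on which untreated library was kept. The median difference was at least as negative as -1.16 with library totals, DESeq2 size factors or without mitochondrially encoded genes. TMM factors ran only from 0.979 (EpH4 untreated replicate 2) to 1.03 (EpH4-AS untreated replicate 2), so these scalings lay close together. They could hardly change this difference, and decide nothing on scaling as its cause. A general damping of changes in EpH4-AS stays open. Of 16 other lists called up in EpH4, 13 had a negative median difference, but lists chosen for their rise in EpH4 tend to fall short in the other line, and among 18 lists called up in EpH4-AS 6 were negative. What also stays open, untested, is a difference in growth between the EpH4 cultures, which may be an effect of the particles or of the culture itself, and the difference between the lines that the design names.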

How the results depend on the processing

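The fits without mitochondrially encoded genes, with thinned EpH4 libraries, with the coding share offset and with the crossed replicate block, and the division of the untreated EpH4 libraries, were chosen after the result was seen.

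The DESeq2 Wald test called 2204 genes for the PM2.5 effect in EpH4, 1004 in EpH4-AS and 1259 for the interaction, against 3726, 1529 and 1932. TREAT against a 1.5-fold change called 184, 40 and 66, as its construction asks for larger changes. Fitted alone, the EpH4-AS groups gave 2995 genes. The counts for EpH4-AS against EpH4 stayed within 1.5 times of 12238 and 12211 under all alternatives run. The cause was not tested for DESeq2 or for the fit to 2 groups. Libraries of a group lay closer in EpH4-AS, where a chi-square of their counts per degree of freedom was 1.52 untreated and 3.19 with PM2.5. In EpH4 this measure, which also grows with depth, was 9.79 and 8.90. The main fit shares its spread between the groups, so it can be wider than that of EpH4-AS alone.

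Without 1 library at a time, the counts ranged from 2145 to 3987 for the PM2.5 effect in EpH4, from 363 to 2088 in EpH4-AS and from 875 to 2621 for the interaction. In EpH4 they were 2451 and 2145 without untreated or PM2.5 replicate 2. Without EpH4-AS untreated replicate 1 or 2, or EpH4-AS PM2.5 replicate 1 or 2, they were 363, 372, 695 and 490 in EpH4-AS and 875, 884, 1141 and 1246 for the interaction. The lone library left in a group is assumed to vary like the other groups, and with fewer libraries the test has fewer degrees of freedom.

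With an estimated correlation, 0 lists were called for the PM2.5 effect in EpH4, 1 in EpH4-AS, 0 and 0 for the lines without and with PM2.5 and 0 for the interaction. In place of camera, fry, which does not compare a list with other genes, called 13 in EpH4-AS, 30 and 33 for the lines and 11 for the interaction. Without 1 library at a time, the lists called for the exposed lines ranged from 7 to 14, the highest without EpH4 PM2.5 replicate 1. The cause was not tested.

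The correlation of the PM2.5 effects was 0.0720 with the stricter filter and from 0.0435 to 0.0821 without 1 library at a time. For the PM2.5 effect in EpH4 set beside the line difference it ranged from 0.0218 (without EpH4 PM2.5 replicate 2) to 0.169 (without EpH4 untreated replicate 1), with 0.144 without EpH4 untreated replicate 2 and 0.0260 without EpH4 PM2.5 replicate 1. With 1 untreated EpH4 library given to each side it was 0.0638 and 0.0571. The cause was not tested. Limma-trend on RPKM moved the median of all genes for the untreated lines from -0.05 to 0.10 on the log2 scale.

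The interaction of Cyp1b1, not called at log2 0.43, was reversed by limma-trend on log2(RPKM + 1), at -0.43 (adjusted p = 0.0297). The added 1 flattens changes at low levels, and Cyp1b1 was lower in EpH4-AS than in EpH4 (log2 -4.16 untreated, -3.73 with PM2.5). The reversal can therefore come from the transform, which was not tested separately. Of 47 called genes named for PM2.5 in EpH4-AS, 27 were lost under an alternative, 8 of them outside TREAT. In EpH4 these were 23 and 3 of 59, for the interaction 24 and 6 of 41. Depth limits genes near the floor, such as Cyp1a1.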

Other observations

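The tests of coding share, of the mesenchymal pattern and of the size of the differences between the lines, the offset for coding share, the thinned libraries and the fit without mitochondrially encoded genes were chosen after the result was seen.

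In EpH4, PM2.5 also raised 9 of 13 measured genes of MHC class I and antigen processing (median log2 0.30; camera adjusted p = 2.51e-06, and adjusted p = 0.239 with an estimated correlation). Of 28 S phase genes 23 rose and 1 fell (median 0.38), and of 24 cholesterol biosynthesis genes 13 rose (median 0.30), with adjusted p = 0.346 and 0.423 with an estimated correlation. Of 17 unfolded protein response genes 12 fell and 1 rose (median -0.22), and of 17 glycolysis genes 10 fell and 1 rose (median -0.20), with adjusted p = 0.423 and 0.304 with an estimated correlation. Of 19 basement membrane genes 9 rose and 1 fell (median 0.22; adjusted p = 0.245 with an estimated correlation). In EpH4-AS, 7 of 17 unfolded protein response genes rose (median 0.22; adjusted p = 0.441 with an estimated correlation), and edgeR called 0 of 28 S phase genes, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-trend.

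Some genes were present in a single line, and those named here were chosen after their values were seen. For these counts, means were taken over all libraries of a line, untreated and exposed. Among genes at 50 CPM or more, 62 in EpH4-AS were under 0.5 CPM in EpH4. In EpH4, 5 were under 0.5 CPM in EpH4-AS, namely Sfrp2, Mgp, Kcnj2, Masp1 and Il33. The first group held Rbm7 and Hexa, which encode an RNA exosome cofactor and a lysosomal enzyme. It also held copies of other genes, namely Eif4a3l1, Eif4a3l2, Rpl27rt, Cox5b-ps, Aldoart1 and Aldoart2, at 68.2 to 169 CPM in untreated EpH4-AS and at most 0.266 CPM in untreated EpH4. Reads shared differently with near-identical copies in the 2 lines were not tested, and stay open for such genes and for ribosomal protein genes. In untreated EpH4, Col1a1 stood at 3.997 CPM beside 1067 CPM for Col1a2, the other chain of collagen I. Of 192 genes needed by most cell types, 191 in EpH4 and 190 in EpH4-AS were at 5 CPM or more.

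The lines differed in 12238 genes, with a median size of log2 1.18. The count was 12198 without mitochondrially encoded genes, 11901 with EpH4 thinned and 12214 after an offset that removes the trend with coding share, but with 89.2% of tested genes called this count is saturated and decides nothing. The median size was 1.17, 1.15 and 1.15 in these fits. Levels were already scaled for library totals, and mitochondrial transcripts took a mean of 4.63% of counts or less in each group. Leaving these transcripts out or thinning EpH4 could therefore hardly change the median, and decides nothing on them or on depth. The trend with coding share, as fitted, accounted for little of the size, as its Spearman's rho of 0.16 already implied. A candidate explanation for part of the pattern is that EpH4-AS reads differ from the mouse reference. Genes with a larger coding share were higher in EpH4-AS (Spearman's rho 0.16 over 13163 genes), and the share of gene reads outside exons was lower in each EpH4-AS library and for 96.3% of 2918 genes with about the same level in both lines. However, 62 genes at 50 CPM or more in EpH4-AS were under 0.5 CPM in EpH4, against 5 the other way. Loss of EpH4-AS reads would not by itself give this direction. Reads of a line from another strain, species or cell line than labelled stay open, and would change what each comparison of the lines means. Long noncoding genes lay at -0.51 log2 against coding genes, but with 20 such genes this cannot be told apart from chance, as coding genes of like level gave -1.26 to 0.64. Transformation, which the design names, stays open and untested.

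Both lines expressed mesenchymal genes and few epithelial ones. The epithelial junction list had a median of 0.134 CPM in untreated EpH4. This argues against a minority of stromal cells among epithelial cells only if these genes were aligned like others. Their loss in the alignment, left open below, would give the same low median whatever the cells. Loss of these genes in the authors' assignment of reads to exons alone is argued against, since reads inside and outside exons had a median of 0.396 CPM at most in an untreated group. Their loss in the authors' alignment stays open, as 11 of 37 at 1 CPM or more, in the group with fewer, cannot be told apart from low expression. Col1a1 was low beside Col1a2, and Rbm7 and Hexa were nearly absent in EpH4, but these genes were picked after their values were seen. In untreated EpH4-AS, Rbm7 and Hexa stood at 72.5 and 236 CPM, so they could be counted there. Col1a1 was low there too, at 0.0933 CPM beside 34.4 CPM for Col1a2. In EpH4, 191 of 192 genes needed by most cell types were at 5 CPM or more. These values do not decide whether epithelial genes were lost. Libraries of a non-epithelial cell type may be a candidate source, but 9 of 18 fibroblast markers at 1 CPM or more, in the group with fewer, cannot be told apart from mesenchymal epithelial cells, since 7 of the 18 are also on the mesenchymal list. In untreated EpH4 and EpH4-AS, Col1a2 stood at 1067 and 34.4 CPM, C3 at 748 and 36.4 CPM and Pdgfra at 362 and 59.2 CPM. A change of epithelial cells towards a mesenchymal state stays open and untested.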
